A study of Mus musculus with 26 samples.

How the data were processed

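Islets were isolated from C57BL/6J mice of 10 weeks. Tamoxifen was given by gavage at 2 mg per day for 5 days, or corn oil in its place, and islets were taken 2 weeks later, per the labels. RNA sequencing covered 16 libraries in 2 experiments: 3 knockout and 3 control libraries in experiment a and 5 of each in experiment b. ChIP-seq of HDAC3 covered 6 libraries and 4 inputs. Groups and replicate numbers were taken from the sample titles and genotypes. The sequencing kit and its strandedness are not given in the sources used here, so reads of overlapping and antisense genes may be counted together.

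The authors deposited normalized read counts per gene and library (a signal that is never negative) for 24328 rows. The submitters' processing notes name HOMER, HTSeq, DESeq2 and DESeq and the build mm9, with no role. Each library's values were whole multiples of a single step, so reads were recovered by dividing by it: 100% of values came out whole within 0.001, and the reciprocals of the steps equalled median-of-ratios size factors over all 16 libraries. For KO_b replicate 1 the step was close to 1 (0.993), so whole reads could not be shown by the same check, and a fit without it was added. The recovered totals were 5257285 to 6668981 reads per library in experiment a and 7084524 to 10777154 in experiment b. The authors also deposited an adjusted p-value per gene and a log2 fold change of knockout over control for each experiment, per the file headers. That log2 fold change equalled the log2 ratio of the group means. A second deposited file lists peak positions of the series without a score, made by the authors from control peaks filtered against the knockout, per its name. Peaks were thus given once for the series and not per sample.

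In the table, 27 rows have a date in place of a gene name, as spreadsheet programs write some symbols. They were tested and counted (4, 2 and 9 of the genes past the threshold in experiment a, experiment b and both) but not named. All per-sample columns of the table were matched to a sample.

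The design was fixed before the data were examined, as were the named-gene rule, the gene lists and most other settings tried. It had foreseen raw counts and edgeR, with limma for normalized values. Because the table holds normalized values, the main test was limma-trend with empirical Bayes moderation on log2(normalized count + 1), for genes with a mean of at least 10 over the libraries fitted. Benjamini-Hochberg adjusted p-values under 0.05 passed. Each experiment was fitted alone, then all 16 libraries with a term for the experiment, then with the interaction of experiment and genotype. Hdac3 was also tested by an exact two-sided permutation of log2 values within each experiment. Analyses used R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, the count tools on the recovered reads. The replicates of each group were compared by a chi-square of their recovered reads, and all pairs differed by more than sampling noise (chi-square per degree of freedom 5.22 to 70.6).

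Named genes were Hdac3, then the 10 largest rises and the 10 largest falls over both experiments together, with a mean of at least 20 and the same direction in each experiment. The 5 largest in each direction in experiments a and b followed, where every knockout library lay on the same side of every control library, then the 5 largest in each direction for the difference between experiments. Up to 4 members of each gene list with the smallest p over both experiments were added. Some genes that the rule names are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

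The 29 gene lists held 474 members, of which 472 were in the table, 4 of them by a synonym looked up after the table was seen. They covered beta cell identity, disallowed genes, dedifferentiation, exocytosis, glycolysis, oxidative phosphorylation, lipid metabolism, cholesterol synthesis, prolactin and growth hormone response, unfolded protein response, cell cycle, immediate early genes, circadian clock, the corepressor complex, neuronal genes, interferon response, NF-kB targets, oestrogen response, growth factors and ligands, ribosomal proteins, and markers of alpha, delta and PP, acinar, duct, endothelial, stellate, macrophage, Schwann and red blood cells. Lists with at least 3 tested members were tested by limma's camera with a preset correlation of 0.01 and with an estimated correlation, and by fry, with Benjamini-Hochberg adjustment over the lists. The camera test of the difference between experiments was added after the data were seen.

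Also chosen then, as other settings, were quantile and upper-quartile scaling, DESeq2, limma-voom, limma without trend, other filters and pseudocounts, a fold threshold of 1.5, the replicate number as a block, a joint fit, and leaving out each library. Added after the data were seen were edgeR on the recovered reads, a fit without Control_a replicate 3 and Control_b replicate 2, and the mean log2 level of the acinar markers as a covariate. No scaling moved the median of all genes by more than 0.1 on the log2 scale.

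The tests were run on simulated reads in which 200 genes picked at random were changed, with the means and depths of the real libraries. The other genes of the cholesterol synthesis list were changed 1.5-fold. Each gene was drawn independently, in a single run per comparison. In experiment a, limma recovered 7.46%, 59.7% and 89.4% of genes changed 1.5-fold, 2-fold and 4-fold among 13704 genes tested, and 8.47% of its calls were false. In experiment b it recovered 28.4%, 70.2% and 93.9% among 13164 genes, with 6.85% false. For both experiments together it recovered 59.7%, 80.6% and 98.5% among 13418 genes, with 6.67% false, and for the difference 5.97%, 23.9% and 83.3% among 13405 genes, with 3.80% false. DESeq2 had 17.8% false calls in the simulation of experiment b.

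Counts of near-identical genes, such as Slco1a5 and its family, Csf2rb and Csf2rb2, the guanylate-binding proteins, Ins1 and Ins2 and the trypsins, are uncertain where reads could be shared. The reference tables used here are of another build than the peaks, so the planned test of peaks within 10 kb of changed genes was not run.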

Results

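Islets, the hormone-secreting cell clusters of the pancreas, were profiled by RNA sequencing in 16 libraries from 2 experiments. In the knockout group of each experiment, Hdac3 was deleted in beta cells, the insulin-secreting cells of the islet. HDAC3 is a histone deacetylase that acts within the NCoR and SMRT corepressor complexes. Experiment a set 3 knockout libraries (KO_a) against 3 libraries of floxed islets from mice given tamoxifen, whose label names no Cre (Control_a). Experiment b set 5 knockout libraries (KO_b) against 5 libraries of floxed islets with Cre from mice given vehicle (Control_b). The kind of control thus changed with the experiment, and these cannot be told apart. Reads assigned to genes ranged from 5257285 to 6668981 per library in experiment a and from 7084524 to 10777154 in experiment b. Between 18725 and 19502 genes had at least 1 read in the libraries of experiment a, and between 16352 and 17065 in those of experiment b. The labels do not say that the libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

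Hdac3 was lower in the knockout of both experiments. In experiment a it reached 229 ± 5.30 normalized counts in the knockout and 372 ± 32.7 in the control (SD, n = 3 each), so that the knockout held 61.6% of the control level. The knockout values lay between 223 and 232 and the control values between 335 and 395. In experiment b it reached 257 ± 50.9 in the knockout and 391 ± 57.9 in the control (SD, n = 5 each), or 65.9%, and the groups overlapped, with knockout values up to 317 and control values down to 298. The exact two-sided permutation test on log2 values gave p = 0.1 in experiment a, the smallest that 3 against 3 allows, and p = 0.0159 in experiment b. Across all genes, limma gave Hdac3 a log2 fold change of -0.69 (SE 0.13, adjusted p = 0.0071) in experiment a. In experiment b it gave -0.61 (SE 0.15, adjusted p = 0.0485), and over both experiments -0.64 (SE 0.11, adjusted p = 0.000655). The call of experiment b was lost in 14 of 25 alternative settings, over which its adjusted p ranged from 0.00858 to 0.342. Among these were the fits without KO_b replicates 1, 2, 4 and 5 (limma adjusted p = 0.0746, 0.0963, 0.13 and 0.0742) and without Control_b replicates 1, 3, 4 and 5 (0.107, 0.0659, 0.126 and 0.0921). The part of Hdac3 that was deleted is not given in the sources used here, and islets also hold cells in which it was not targeted.

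**Figure D1:**
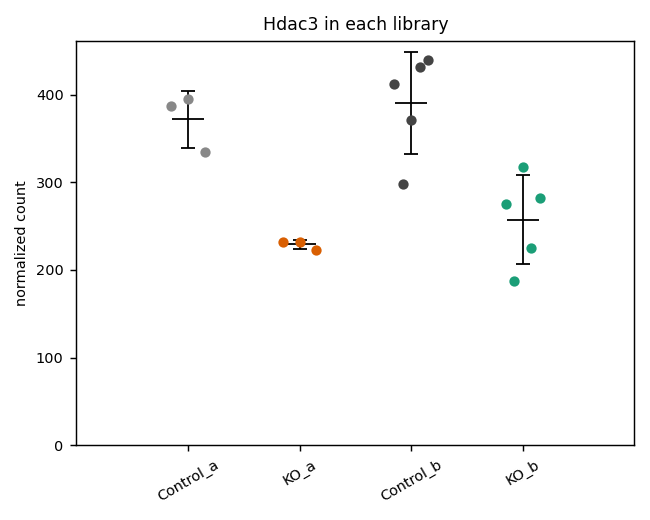
Hdac3 in normalized counts (vertical axis, from 0) for each library, by group (horizontal axis). Points are libraries and bars give the mean ± SD (n = 3 per group in experiment a, n = 5 in experiment b). The knockout means are 229 and 257, and the control means 372 and 391.

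The libraries differed in the RNA of other cell types and in insulin transcripts. Transcripts of Ins1 and Ins2, the mouse insulin genes, made up 13.2% ± 6.96 of the reads in Control_a and 4.20% ± 0.771 in KO_a (SD, n = 3 each), and 13.7% ± 3.87 in Control_b and 9.77% ± 0.799 in KO_b (SD, n = 5 each). Control_a replicate 3 held 21.2% and Control_b replicates 1 and 2 held 19.1% and 16.4%. Markers of acinar cells, the enzyme-secreting cells that surround the islets, had a mean log2 level of 7.90 ± 1.79 in Control_a and 7.56 ± 1.24 in KO_a (SD, n = 3 each). In experiment b they reached 8.997 ± 0.466 in Control_b and 7.35 ± 1.41 in KO_b (SD, n = 5 each). On the first principal component (26.6% of the variance) the libraries of experiment a had scores below 0 and those of experiment b above 0, except Control_b replicate 2, at -26.8. On the third component (12.1%), Control_b replicate 2 had the highest score, 48.0. That library stood apart from the other controls of experiment b for Myc, Pkm, Atp5a1, Atf4, Mki67, Celf4, Gdf15, Kdr and Rpl27. KO_b replicate 2 did so among the knockouts for Tph1, Csf2rb2, Crispld2 and Cxcl10.

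**Figure D2:**
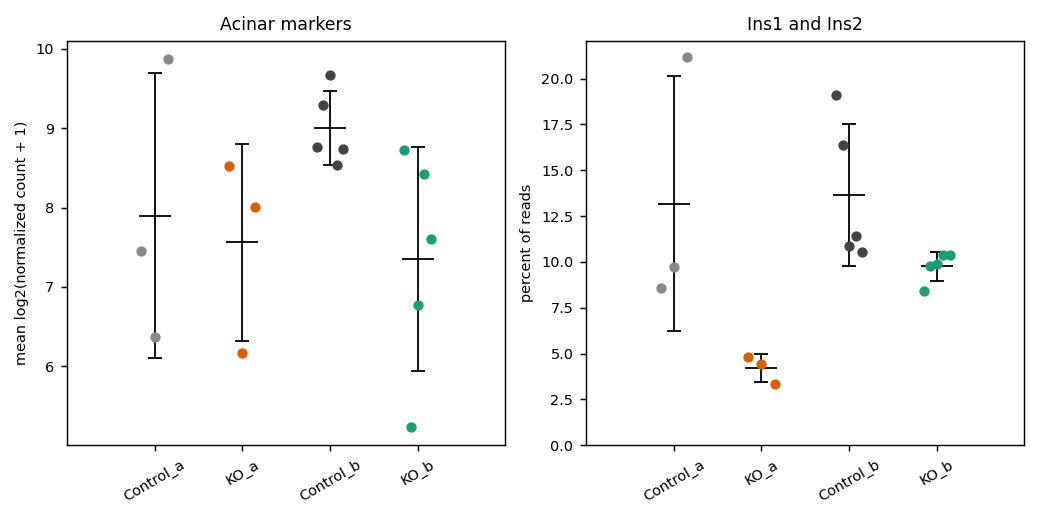
Mean log2(normalized count + 1) of the acinar markers (left) and percent of reads from Ins1 and Ins2 (right) for each library, by group. Points are libraries and bars give the mean ± SD (n = 3 per group in experiment a, n = 5 in experiment b). Acinar markers averaged 8.997 in Control_b and 7.35 in KO_b, and the insulin genes 13.2% in Control_a and 4.20% in KO_a.

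Experiment a compared islets lacking Hdac3 in beta cells with floxed islets that had also been exposed to tamoxifen. Csf2rb, the shared beta subunit of the GM-CSF, IL-3 and IL-5 receptors, rose from 14.3 ± 5.82 to 4873 ± 1567 normalized counts (SD, n = 3 each; log2 fold change 8.34, SE 0.31, limma adjusted p = 3.67e-07). Tph1, which encodes the enzyme of the rate-limiting step of serotonin synthesis, rose from 3.98 ± 3.60 to 867 ± 123 (log2 fold change 7.89, SE 0.63). The libraries of Control_b, whose label names Cre, held 390 to 1958 normalized counts of Tph1. Control_b was not labelled a knockout, so the knockout alone does not account for high Tph1 counts there. In experiment a, Cre and the knockout changed together and cannot be told apart as the source of this rise. Sgcz, a sarcoglycan gene, fell by 3.73 on the log2 scale (SE 0.35), from 69.1 ± 2.78 to 4.53 ± 2.06. Reads assigned to Esr1, the gene of oestrogen receptor alpha, went from 13.4 ± 3.25 to 10016 ± 1319 (log2 fold change 9.46, SE 0.18, adjusted p = 1.8e-09). They were also at 8626 ± 2538 in Control_b (SD, n = 5), whose label names Cre, and tamoxifen-dependent forms of Cre carry part of an oestrogen receptor. The Cre line is not given in the sources used here, so reads of Esr1 and of such a transgene cannot be told apart. In all, 1566 of 13722 genes passed the limma test at an adjusted p under 0.05, with 821 higher and 745 lower in the knockout, and 1280 of them changed by at least 1.5-fold. Another large rise was that of Gbp11, a member of the interferon-inducible guanylate-binding proteins (8.21, SE 0.70). Control_b held 53.2 to 229 normalized counts of Csf2rb and 64.9 to 276 of Gbp11, against at most 19.8 and 9.40 in Control_a. For both rises, Cre and the knockout cannot be told apart in experiment a. Falls were found for Shisa2, an inhibitor of Wnt and FGF signalling (-3.44), the potassium channel gene Kcnh5 (-3.30), the cation channel gene Trpc4 (-3.18) and the uroplakin gene Upk3a (-3.08). Every knockout library lay on the same side of every control library for each of these genes, which was a condition of naming them and adds no support. For a single gene, 10.0% of groupings of 3 against 3 give this by chance. Without KO_a replicate 2, KO_a replicate 3 or Control_a replicate 2, the count of genes fell to 597, 719 and 744. The fold changes are on the log2(value + 1) scale and understate the change of genes near 0.

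Genes that respond to prolactin and growth hormone formed the list with the largest shift in experiment a, where 13 of its 16 members were lower in Control_a than in Control_b. Of its 16 members, 11 rose and none fell, and 11 rose when adjusted over the list alone (median log2 fold change 1.86). The camera test gave an adjusted p = 7.75e-11, and an adjusted p = 0.231 with an estimated correlation. Socs2, an inhibitor of cytokine signalling, rose by 2.46 (adjusted p = 1.06e-05), Ivd, an enzyme of leucine breakdown, by 2.05 (adjusted p = 1.22e-05), and Prlr, the prolactin receptor, by 1.07 on the log2 scale (adjusted p = 0.00801). Among members chosen after their values were seen, Tph2, the second tryptophan hydroxylase gene, rose by 2.29 and Cish, a target of STAT5, by 2.57. Of 28 genes of beta cell identity and insulin secretion, 9 fell and none rose, and 16 fell and 2 rose when adjusted over the list alone (camera adjusted p = 0.000444; adjusted p = 0.837 with an estimated correlation). Without each library in turn, between 4 and 12 of the 28 fell, with 4 without KO_a replicate 2 and without Control_a replicate 2. Ins1 fell from 280292 ± 110401 to 89817 ± 18550.1 (log2 fold change -1.60, adjusted p = 0.0122), and Nkx6-1, a transcription factor of mature beta cells, from 439.7 ± 64.3 to 219 ± 69.7 (log2 fold change -1.04, adjusted p = 0.0148). Ucn3, a hormone of mature beta cells that was also chosen after its values were seen, fell by 1.40 (adjusted p = 2.29e-05). The call of Ins1 was lost in 2 of 20 alternative settings, 1 of them without KO_a replicate 2 (adjusted p = 0.0637, the highest of a range from 1.98e-11), and Ins2 had a log2 fold change of -1.43 with an adjusted p = 0.0785.

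A further 5 lists passed the preset camera test in experiment a, all of them with an adjusted p = 0.0203, and with an estimated correlation the adjusted p was 0.837 for each. Of 18 genes of the unfolded protein response, 3 rose, and 5 when adjusted over the list alone, among them Trib3, a stress-induced pseudokinase (2.69, adjusted p = 0.00379), and Asns, asparagine synthetase (0.81, adjusted p = 0.00703). Of 11 markers of alpha cells, the glucagon-secreting cells, 1 fell, and 3 when adjusted over the list alone. Slc7a2, an arginine transporter on that list, fell by 1.11 (adjusted p = 0.00103). Of 18 immediate early genes, 1 fell over all genes and over the list alone, which was Egr1, an activity-induced transcription factor (log2 fold change -1.26, adjusted p = 0.00797). Oxidative phosphorylation genes shifted up with 1 of 19 passing on its own, also when adjusted over the list alone (median 0.22), and Ndufa4, a subunit of the respiratory chain, rose by 0.56 (adjusted p = 0.0229). The endothelial markers shifted up with 0 of 11 members passing, also when adjusted over the list alone (median 0.43). Leaving out 1 library ended the calls of the unfolded protein response (KO_a replicate 3, Control_a replicates 2 and 3; adjusted p = 0.121, 0.0829 and 0.111), alpha cell (KO_a replicate 2, Control_a replicate 3; 0.075 and 0.116) and immediate early lists (KO_a replicates 2 and 3, Control_a replicate 2; 0.114, 0.0545 and 0.207). It also did so for oxidative phosphorylation (KO_a replicates 2 and 3, Control_a replicates 2 and 3; 0.0703, 0.0527, 0.0693 and 0.142) and endothelial markers (KO_a replicate 1, Control_a replicates 1 and 2; 0.106, 0.159 and 0.0594). Without each library in turn, the members past the threshold numbered 1 to 7 for the unfolded protein response (1 without KO_a replicate 2), 1 to 3 for alpha cell markers, 1 to 7 for immediate early genes, 0 to 6 for endothelial markers and 0 to 1 for oxidative phosphorylation (0 without KO_a replicates 2 and 3 and Control_a replicate 2). Acinar markers, which varied between libraries, had a median of -0.37 and a camera adjusted p = 0.499.

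Experiment b compared islets lacking Hdac3 in beta cells with islets that carried Cre and had received vehicle. Slco1a5, an organic anion transporter, rose from 20.8 ± 6.80 to 219.7 ± 83.1 normalized counts (SD, n = 5 each; log2 fold change 3.30, SE 0.28, limma adjusted p = 6.19e-05). The uncharacterised transcript 6330403K07Rik rose from 40.6 ± 10.6 to 397 ± 166 (log2 fold change 3.18, SE 0.27, adjusted p = 6.19e-05). Derl3, a component of the degradation of misfolded proteins from the endoplasmic reticulum, fell from 254 ± 75.4 to 37.0 ± 11.7 (log2 fold change -2.74, SE 0.25, adjusted p = 0.000119). Egf, which encodes epidermal growth factor, fell from 449 ± 82.3 to 101 ± 30.1 (log2 fold change -2.18, SE 0.21, adjusted p = 0.000138). The limma test passed 395 of 13178 genes, 200 higher and 195 lower in the knockout, and 256 of them changed by at least 1.5-fold. Rgs8, a regulator of G protein signalling, rose by 2.99 (SE 0.38), Gm4791 by 2.52 (SE 0.28) and Tmem40 by 3.24 on the log2 scale (SE 0.76). Falls were found for Ngfr, a neurotrophin receptor (-2.40), the transcription factor Myc (-2.32) and the secreted protein gene Crispld2 (-2.26). Myc reached 136 normalized counts in Control_b replicate 2 and between 19.9 and 45.9 in the other controls, and the call of Tmem40 was lost in 10 of 24 alternative settings. With the acinar marker level as a covariate, 32 genes passed and the median standard error of the 395 genes rose from 0.14 to 0.19, while DESeq2 passed 923 and a single fit of all 16 libraries 658. The count was 208, 196, 130 and 204 without KO_b replicates 1, 2, 4 and 5, and 192 and 131 without Control_b replicates 1 and 4.

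Acinar markers, lower in KO_b than in Control_b, were the list with the largest shift in experiment b. None of the 18 passed over all genes and 18 fell when adjusted over the list alone (median log2 fold change -1.79; camera adjusted p = 1.17e-09; adjusted p = 0.596 with an estimated correlation). Try5, a trypsin gene, had 843 ± 283 normalized counts in the control and 312 ± 244 in the knockout, and Cpa1, a carboxypeptidase, 1908 ± 697 and 721 ± 571 (SD, n = 5 each). Of 17 cholesterol synthesis genes, 5 rose and none fell, and 6 rose when adjusted over the list alone (camera adjusted p = 2.71e-05; adjusted p = 0.507 with an estimated correlation). Without each library in turn, between 1 and 6 of the 17 rose, with 1 without KO_b replicate 4 and without Control_b replicate 4. Msmo1, a sterol oxidase, rose by 1.10 (adjusted p = 0.0146), Fdft1, squalene synthase, by 0.73 (adjusted p = 0.00691) and Fdps, farnesyl diphosphate synthase, by 0.77 (adjusted p = 0.0346). Oxidative phosphorylation genes shifted up with 1 of 19 passing, also when adjusted over the list alone, Cox6a2 (1.60, adjusted p = 0.0292; list camera adjusted p = 0.000107; adjusted p = 0.764 with an estimated correlation). Of 9 markers of delta and PP cells, 1 rose, also when adjusted over the list alone, the retinol-binding protein gene Rbp4 (0.76, adjusted p = 0.00674; list camera adjusted p = 0.0109; adjusted p = 0.507 with an estimated correlation). The prolactin and growth hormone list shifted down, with 1 of 16 passing, Tph2 (-1.77, adjusted p = 0.0237), and 3 when adjusted over the list alone (camera adjusted p = 0.0109; adjusted p = 0.804 with an estimated correlation). Neuronal genes shifted down with 1 of 15 passing and 3 when adjusted over the list alone (camera adjusted p = 0.0486; adjusted p = 0.507 with an estimated correlation). The gene that passed was Grin1, a subunit of the NMDA receptor (-0.56, adjusted p = 0.0333). Ribosomal protein genes shifted up with 0 of 19 passing, also when adjusted over the list alone (median 0.14; camera adjusted p = 0.0486; adjusted p = 0.81 with an estimated correlation). Leaving out 1 library ended the calls of the neuronal (KO_b replicates 1 and 4, Control_b replicates 2, 3 and 5; adjusted p = 0.0794, 0.0749, 0.13, 0.0537 and 0.074) and ribosomal lists (KO_b replicates 1, 3 and 4, Control_b replicates 1 and 2; 0.205, 0.0861, 0.0817, 0.0709 and 0.733). Without KO_b replicate 3, the delta and PP cell list (0.0861) and the prolactin and growth hormone list (0.0647) were lost too. With 1 library left out, the single member that passed was lost without KO_b replicates 1, 2, 4 and 5 and Control_b replicate 4 for oxidative phosphorylation, and without KO_b replicate 4 and Control_b replicates 1 and 4 for the prolactin and growth hormone list. For the neuronal list this was so without KO_b replicates 1 to 4 and Control_b replicates 1, 4 and 5. Of the 28 beta cell identity genes none passed limma over all genes or adjusted over the list alone, and Ins1 had 372266 ± 97711 normalized counts in the control and 253991 ± 17094 in the knockout.

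**Figure D3:**
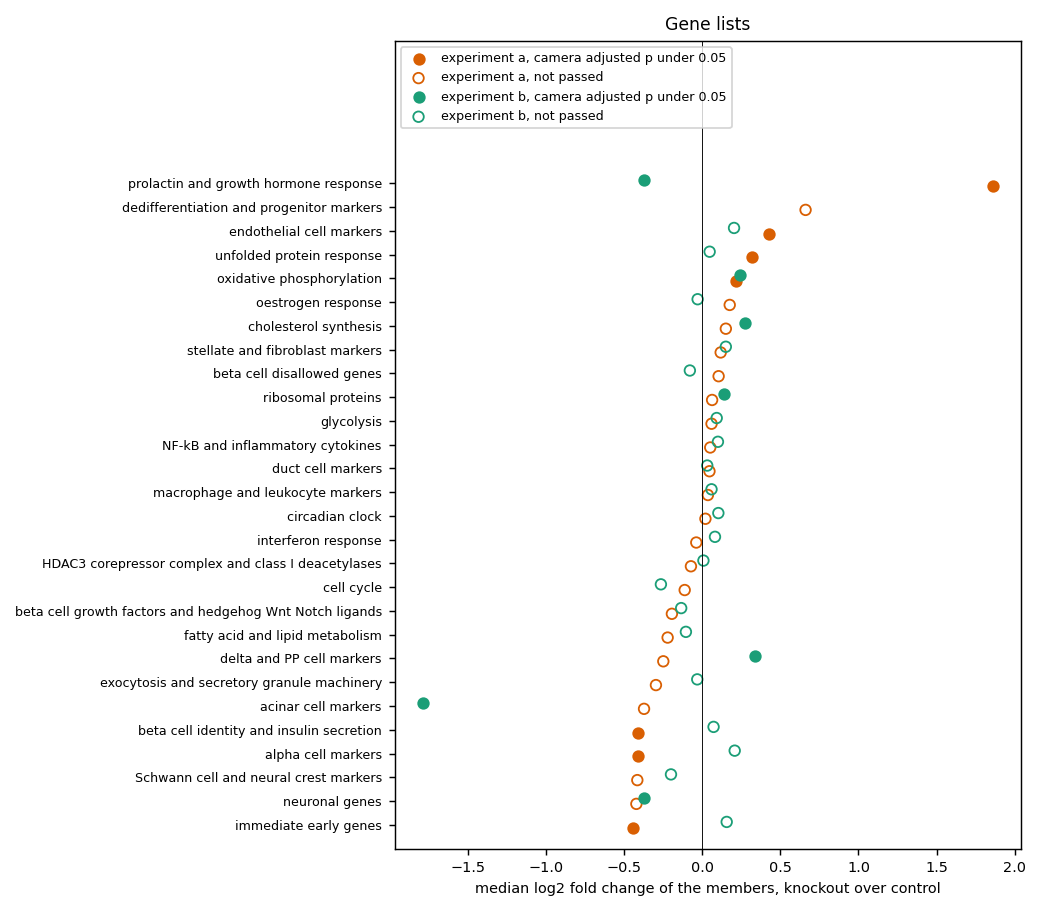
Median log2 fold change of knockout over control (horizontal axis) of the members of each gene list (vertical axis) in experiment a (orange) and experiment b (green). Filled points passed the camera test with the preset correlation at an adjusted p under 0.05 and open points did not. The prolactin and growth hormone list lies at 1.86 in experiment a and -0.37 in experiment b, and the acinar markers at -0.37 and -1.79.

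Fitted together with a term for the experiment, the 16 libraries gave the mean effect of the knockout over both kinds of control. Slco1a5 rose by 3.30 (SE 0.19, limma adjusted p = 8.65e-09) and 6330403K07Rik by 3.12 on the log2 scale (SE 0.19, adjusted p = 1.31e-08), and each had close values in both experiments. Slco1a5 went from 23.9 ± 1.49 to 244.04 ± 28.04 in experiment a (SD, n = 3 each), a log2 fold change of 3.30 beside 3.30 in experiment b. The log2 fold change was -1.89 for Egf (SE 0.18, adjusted p = 2.84e-06), -2.01 for Myc (SE 0.33, adjusted p = 0.000655) and -2.62 for Upk3a (SE 0.43, adjusted p = 0.000655). The subunits of the NCoR and SMRT complexes Tbl1xr1 and Tbl1x rose by 1.25 (adjusted p = 1.73e-06) and 0.85 (adjusted p = 2.92e-05). The test passed 2377 of 13408 genes, 1222 higher and 1155 lower, and 2371 of these had the same sign in each experiment. Effects of opposite sign cancel in this fit and seldom pass it, so that count adds no support. Prr29 rose by 2.67 (3.19 in experiment a and 2.36 in experiment b). For other genes with a large mean rise, experiment a contributed most: Tmem40 had 6.80 and 3.24, Csf2rb 8.34 and 1.36, and Car8, a carbonic anhydrase-related gene, 5.34 and 1.51 in experiments a and b. Car8 was higher in Control_b (687 to 1599 normalized counts) than in Control_a (202 to 233), as were Csf2rb and Gbp11, while Csf2rb2 was not (0.782 to 7.26 against 2.48 to 7.05). The same held for Csf2rb2, a near-identical copy of Csf2rb (6.72 and 1.94), for Gbp11 (8.21 and 1.02) and for the reads assigned to Esr1 (9.46 and 0.22), whose joint call was lost in 8 of 29 alternative settings. Shisa2, Derl3, Ngfr, Sgcz, Cecr6, Trpc4 and Rassf10 were the other large falls, with log2 fold changes of -1.90, -1.89, -1.84, -1.80, -1.73, -1.59 and -1.53. The joint call of Ngfr was lost in 12 of 28 alternative settings, among them leaving out KO_a replicate 3, Control_a replicates 2 and 3, KO_b replicates 1, 2 and 3 and Control_b replicates 1, 2 and 4 (adjusted p = 0.068, 0.0604, 0.0603, 0.0574, 0.0638, 0.0508, 0.0633, 0.0501 and 0.0622). Of the 2377 genes, 800 changed by at least 1.5-fold, and 202 genes passed with the same sign in each experiment fitted alone. In a separate fit with the acinar marker level as a covariate, 1240 genes passed.

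In the joint fit of both experiments, oxidative phosphorylation and cholesterol synthesis genes shifted up. Cholesterol synthesis did not pass in experiment a alone, where 4 of 17 rose and 1 fell (median 0.15, camera adjusted p = 0.314). Its effect was higher in experiment b by the preset camera test (adjusted p = 0.0245, and 0.554 with an estimated correlation). Of 19 oxidative phosphorylation genes 5 rose, and 8 when adjusted over the list alone (camera adjusted p = 0.000631; adjusted p = 0.802 with an estimated correlation), such as Ndufa4 (0.45, adjusted p = 0.00691) and Sdhb, a subunit of succinate dehydrogenase (0.30, adjusted p = 0.0226, and 0.0513 without KO_a replicate 3). Of 17 cholesterol synthesis genes 7 rose, and 7 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.00318; adjusted p = 0.802 with an estimated correlation), such as Msmo1 (1.18) and Idi1, isopentenyl diphosphate isomerase (0.71). Endothelial markers shifted up (2 of 11 rose, also when adjusted over the list alone; camera adjusted p = 0.0371; adjusted p = 0.802 with an estimated correlation), with Kdr, a receptor of VEGF, at 0.36 (adjusted p = 0.0213). Acinar markers shifted down with none of 17 passing, also when adjusted over the list alone (median -1.26; camera adjusted p = 0.00163; adjusted p = 0.802 with an estimated correlation). Without each library in turn, 3 to 7 oxidative phosphorylation genes rose (3 without KO_a replicate 3) and 1 to 4 endothelial markers (1 without KO_a replicate 2, KO_b replicate 4 and Control_b replicate 4). The endothelial call was lost without KO_a replicates 1 and 2, Control_a replicates 1 and 2, KO_b replicates 3 and 4 and Control_b replicates 3 and 5 (0.0833, 0.0546, 0.119, 0.0677, 0.0804, 0.0808, 0.0667 and 0.0707). Of 21 exocytosis and granule genes 3 rose and 6 fell, and 4 and 9 did so when adjusted over the list alone (camera adjusted p = 0.29). Chga, the granule protein chromogranin A, rose from 102665 ± 22467 to 227535 ± 25468 normalized counts in experiment b (SD, n = 5 each; joint log2 fold change 1.22, adjusted p = 5.02e-05), and Snap25, a SNARE protein of exocytosis, fell by 0.42 (adjusted p = 0.00172). Of 28 beta cell identity genes 4 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.423). The falls numbered 2 when KO_a replicate 2 or 3 or Control_a replicate 2 or 3 was left out. Iapp, which encodes amylin, rose by 0.67 (adjusted p = 0.0103), while Ins1 fell by 0.92 (adjusted p = 0.00897) and Nkx6-1 fell by 0.70 (adjusted p = 0.0167).

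The other lists did not pass the camera test over both experiments. Of 12 corepressor complex and class I deacetylase genes 3 rose and 1 fell, and 3 and 2 did so when adjusted over the list alone (camera adjusted p = 0.434), with Hdac2 at 0.32 (adjusted p = 0.0179). Of 9 growth factor and hedgehog, Wnt and Notch ligand genes 2 rose and 3 fell, and 2 and 4 when adjusted over the list alone (camera adjusted p = 0.559). They included Vegfa, the vascular endothelial growth factor (0.47, adjusted p = 0.000171), and the ligand gene Wnt4 (-0.86, adjusted p = 0.00267). Of 15 neuronal genes 5 fell, and 6 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.0793). Of 16 glycolysis genes 4 rose, also when adjusted over the list alone (camera adjusted p = 0.274), with Aldoa, an aldolase, at 0.29 (adjusted p = 0.00856). Of 21 lipid metabolism genes 2 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.429), with 1 that rose when KO_a replicate 2 or 3 or Control_a replicate 3 was left out, and the gene that fell was Lpl, lipoprotein lipase (-1.02, adjusted p = 0.000655). Of 4 dedifferentiation and progenitor markers 2 rose, also when adjusted over the list alone (camera adjusted p = 0.0901): Gast, which encodes gastrin (2.78, adjusted p = 0.000576), and Neurog3, the endocrine progenitor factor (1.12, adjusted p = 0.00331), with 1 past the threshold without KO_a replicate 3. Gast had 3 reads in each library of Control_a and 0 to 1 in those of Control_b, so the size of its rise is uncertain. Its call was kept in 27 of 27 alternative settings, with log2 fold changes of 1.25 to 3.90. Of 19 circadian clock genes 1 rose and 3 fell, and 2 and 3 when adjusted over the list alone (camera adjusted p = 0.843). The calls of Dbp, which rose, and of Cry2 and Per1, which fell, were lost in 11, 14 and 13 of 29 alternative settings. A single gene of that list fell when KO_a replicate 2 or 3, Control_a replicate 2 or 3, KO_b replicate 1 or 2 or Control_b replicate 2, 4 or 5 was left out. Of 19 cell cycle genes 2 fell, and 7 fell and 2 rose when adjusted over the list alone (camera adjusted p = 0.213). Of these Ccnd3, a D-type cyclin, lost its call in 16 of 29 alternative settings, and between 1 and 6 genes fell without each library in turn. Pkm, 1 of the 4 glycolysis genes, lost its call in 16 of 29.

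Among the markers of other cell types, counts over all genes and adjusted over the list alone were the same unless stated. Of 13 stellate and fibroblast markers 2 rose, Sparc and Rgs5 (camera adjusted p = 0.339), and of 11 macrophage and leukocyte markers 2 rose, Lyz2 and Tyrobp (camera adjusted p = 0.339). Of 9 duct markers Krt7 rose and Cftr fell, and 2 rose when adjusted over the list alone (camera adjusted p = 0.952). Of 11 alpha cell markers Gcgr, the glucagon receptor, rose (0.56) and Slc7a2 fell (-0.59), and 2 fell when adjusted over the list alone (camera adjusted p = 0.606). Rbp4 rose among 9 delta and PP cell markers (1.00; camera adjusted p = 0.339) and Ngfr fell among 4 Schwann cell and neural crest markers (camera adjusted p = 0.396). The list of 13 genes that beta cells normally keep low had a camera adjusted p of 0.969. Of 18 unfolded protein response genes 2 rose and 1 fell (camera adjusted p = 0.274). Egr1 was the gene that fell among 16 immediate early genes, with none adjusted over the list alone (camera adjusted p = 0.432), and Rps14 the gene that rose among 19 ribosomal protein genes, likewise with none (camera adjusted p = 0.0901). Among 5 oestrogen response genes, the one that passed was Esr1, whose reads were low in Control_a and not in Control_b and could include those of a Cre transgene (camera adjusted p = 0.714). The calls of Rgs5, Rps14 and Egr1 were lost in 15, 17 and 20 of 29 alternative settings, and that of Ngfr in 12 of 28. None passed limma among 16 prolactin and growth hormone response genes (camera adjusted p = 0.339), 16 interferon response genes (camera adjusted p = 0.714) and 9 inflammatory genes of the NF-kB list (camera adjusted p = 0.429). Red blood cell genes had too few members past the filter for a list test, and Alas2, an enzyme of haem synthesis, had a log2 fold change of 0.54 (adjusted p = 0.0614). The median, the mean and the camera direction differed in sign over both experiments for the corepressor, disallowed and duct lists. They also did so in experiment a for the corepressor, interferon, duct, circadian and stellate lists, in experiment b for the disallowed and duct lists, and in the difference for the cell cycle, interferon, neuronal, glycolysis and oxidative phosphorylation lists, none of which passed there.

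The knockout effect differed between the experiments for 223 of 13408 genes by limma's interaction test, with the effect higher in experiment b for 56 and lower for 167. Here and below, a higher or lower effect refers to the log2 fold change with its sign, not to its size. Tph1 had 3.98 ± 3.60 normalized counts in Control_a and 867 ± 123 in KO_a (SD, n = 3 each), and 939 ± 639 in Control_b and 594 ± 909 in KO_b (SD, n = 5 each). The difference in effect, experiment b minus experiment a, was -9.55 (SE 1.28, adjusted p = 0.000379). Reads assigned to Esr1 reached 8626 ± 2538 in Control_b and 10716 ± 5814 in KO_b (SD, n = 5 each), against 13.4 ± 3.25 in Control_a, a difference in effect of -9.24 (SE 0.45, adjusted p = 9.32e-10). Cldn8, a tight junction gene, and Dnah8, an axonemal dynein gene, had differences of -7.78 (SE 0.98) and -7.31 (SE 0.67), and Gbp11 one of -7.19 (SE 0.96). The calls of Tph1, Cldn8 and Gbp11 were each lost in 1 of 29 alternative settings, limma-voom, with adjusted p-values of 0.316, 0.127 and 0.121 (lowest over the settings 6.21e-06, 1.83e-08 and 3.07e-08). Higher effects in experiment b were found for Sgcz (3.09), the imprinted gene Nnat (2.69), the calcium sensor gene Vsnl1 (2.63), Dapl1 (2.56) and Trpc4 (2.54). Each of these genes was lower in every library of KO_a than in every library of Control_a, and its groups overlapped in experiment b. Of these, Sgcz, Vsnl1, Dapl1 and Trpc4 lost their calls in 11, 10, 15 and 12 of 28 alternative settings. DESeq2 passed 351 genes and limma-voom 124, and the count was 121, 129 and 365 without KO_a replicate 2, KO_a replicate 3 and KO_b replicate 2.

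The effect differed for 9 lists by the preset camera test, and for 1, beta cell identity, also with an estimated correlation. Of its 28 genes 2 had a higher effect in experiment b, Ucn3 (1.46, adjusted p = 0.000575) and the cation channel gene Trpm5 (1.30, adjusted p = 0.00788), both chosen after their values were seen, and 9 when adjusted over the list alone (median 0.36; camera adjusted p = 8.9e-10; adjusted p = 0.0451 with an estimated correlation). The median log2 fold change of that list was -0.41 in experiment a and 0.07 in experiment b. Of 16 prolactin and growth hormone response genes 9 had a lower effect in experiment b, and 11 when adjusted over the list alone (median -2.16; camera adjusted p = 3.45e-17; adjusted p = 0.0509 with an estimated correlation). Socs2 had 167 ± 4.06 normalized counts in Control_a, 934 ± 200.3 in KO_a (SD, n = 3 each), 723 ± 186 in Control_b and 579 ± 153 in KO_b (SD, n = 5 each; difference -2.77, adjusted p = 5.93e-05). The oestrogen response list passed with 1 of 5 genes, Esr1 itself, also when adjusted over the list alone (camera adjusted p = 0.00296; adjusted p = 0.0713 with an estimated correlation). The alpha cell list had 1 of 11 genes with a higher effect in experiment b, Slc7a2, and 3 when adjusted over the list alone (camera adjusted p = 4.51e-05; adjusted p = 0.156 with an estimated correlation). The exocytosis list had 1 gene of 21 with a lower effect, and 4 with a higher and 1 with a lower effect when adjusted over the list alone (camera adjusted p = 0.0239; adjusted p = 0.372 with an estimated correlation). The alpha cell gene was lost without 10 of the 16 libraries (KO_a replicates 2 and 3, Control_a replicates 2 and 3, KO_b replicates 1, 3 and 5 and Control_b replicates 1, 3 and 4). No single gene passed over all genes in the immediate early list (median 0.72, camera adjusted p = 0.000108), the unfolded protein response (-0.23, adjusted p = 0.00746), cholesterol synthesis (0.12, adjusted p = 0.0245) and acinar markers (-1.39, adjusted p = 0.00874). With an estimated correlation the adjusted p was 0.554, 0.554, 0.554 and 0.841 for these lists in the same order. When adjusted over the list alone, 2 immediate early genes and 2 unfolded protein response genes passed, and none of the other lists in that group. Leaving out 1 library ended the calls of the acinar (KO_a replicate 1, Control_a replicate 2, KO_b replicate 2; adjusted p = 0.183, 0.462 and 0.138), exocytosis (KO_a replicates 2 and 3, KO_b replicate 2, Control_b replicate 5; 0.0502, 0.0517, 0.128 and 0.0547) and unfolded protein response lists (KO_a replicate 3, Control_a replicate 3; 0.0651 and 0.058). For cholesterol synthesis these were KO_a replicates 1 and 2, Control_a replicate 2, KO_b replicates 1 and 2 and Control_b replicate 1 (0.183, 0.0502, 0.213, 0.0738, 0.128 and 0.0506).

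**Figure D4:**
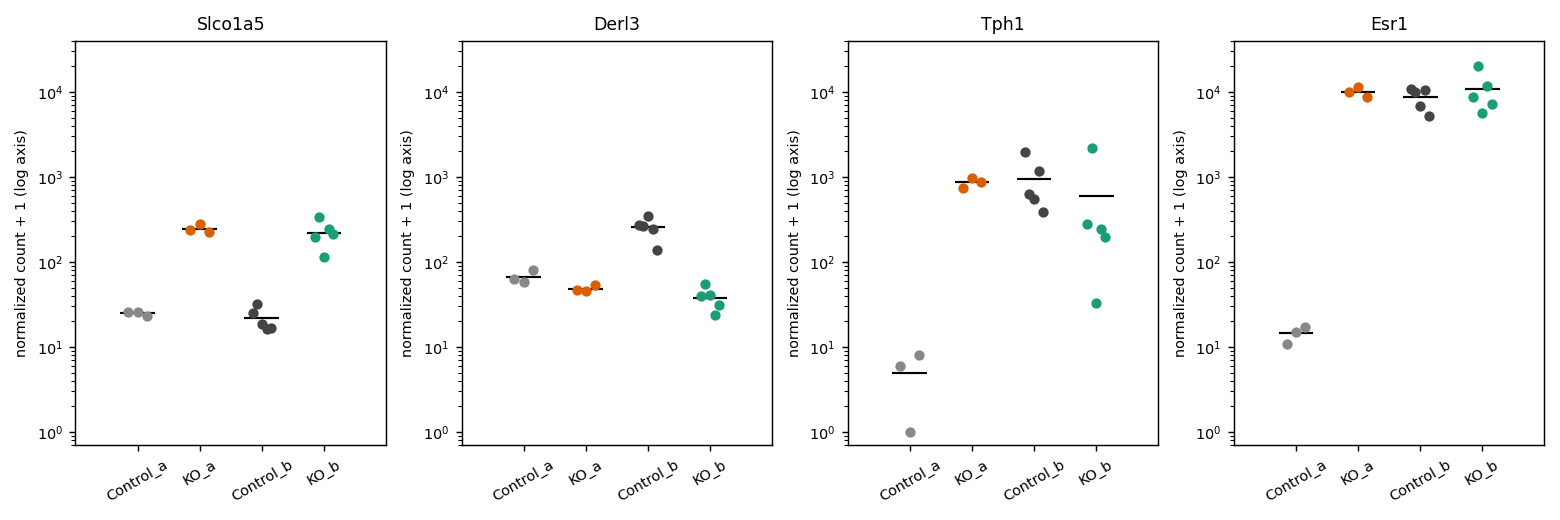
Normalized counts plus 1 (vertical axis, log scale) of Slco1a5, Derl3, Tph1 and Esr1 for each library, by group (horizontal axis). Points are libraries and horizontal lines group means (n = 3 per group in experiment a, n = 5 in experiment b). Slco1a5 is higher in both knockouts, while Esr1 and Tph1 are low in Control_a, with mean counts of 13.4 and 3.98.

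Across the 13057 genes tested in both experiments, the log2 fold changes had a Pearson correlation of 0.434 and a Spearman correlation of 0.540, over genes that are not independent replicates. No library was shared between the experiments. Slco1a5, 6330403K07Rik, Chga and Msmo1 were among the 117 genes that rose in each experiment, where independent lists of these sizes would share 12.2. Egf, Myc and Hdac3 were among the 85 that fell in each, where 10.5 would be shared, and 8 genes passed in opposite directions. Crispld2 was one of these, with 1.88 in experiment a and -2.26 in experiment b (difference -4.13, adjusted p = 0.0055). Of 386 genes past the threshold in experiment b and tested in experiment a, 352 (91.2%) had the same sign there, and of 1533 past it in experiment a, 1293 (84.3%) had the same sign in experiment b.

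**Figure D5:**
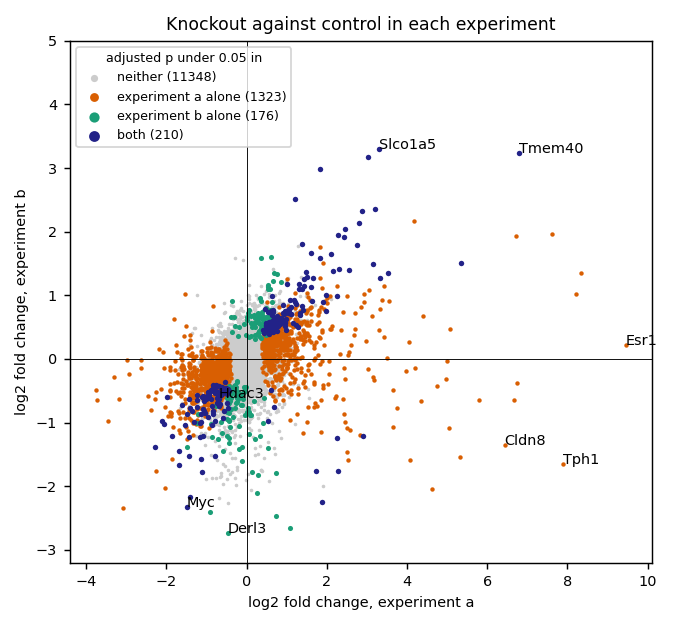
Log2 fold change of knockout over control in experiment a (horizontal axis) and experiment b (vertical axis) for 13057 genes. Each point is a gene, coloured by the experiment in which it passed limma at an adjusted p under 0.05 (1323 in experiment a alone, 176 in experiment b alone, 210 in both). Esr1 lies at 9.46 and 0.22, and Slco1a5 at 3.30 and 3.30.

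The authors' deposited table also gives their own fold changes and adjusted p-values. In the authors' deposited table, 1655 genes had an adjusted p under 0.05 in experiment a, 856 higher, 798 lower and 1 without a listed fold change, and 924 in experiment b, 464 higher and 460 lower. Of the genes past the limma threshold, 1421 of 1566 in experiment a and 388 of 395 in experiment b were also under 0.05 in the authors' deposited table. For Hdac3, the authors' deposited table lists log2 fold changes of -0.70 in experiment a (adjusted p = 0.0013) and -0.60 in experiment b (adjusted p = 0.00765). For Slco1a5, the authors' deposited table lists 3.35 and 3.40. In experiment b it lists -0.55 for Ins1 (adjusted p = 0.00962), which did not pass limma here, and -0.42 for Ins2 (adjusted p = 0.26).

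HDAC3 occupancy was profiled by ChIP-seq, with 3 control and 3 knockout libraries and 2 inputs of each, and was analysed from 1 list of peak positions for the series. The list held 8975 peaks of 200 bp each on 20 chromosomes of mm9, covering 1795000 bp, with a median gap of 94477 bp between neighbours. Chromosome 2 held 699 peaks (7.79%) and the X chromosome 134 (1.49%). Of all peaks, 2202 (24.5%) lay within 10000 bp of another, in 991 groups. The groups with the most peaks held 7 each, on chromosome 1 from 191970832 to 191985839 and on chromosome 2 from 147777433 to 147810622. The list had no height or score, so no peak was ranked, and no annotation of that build was used here, so the peaks were not assigned to genes. No replicate measure of occupancy was analysed here.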

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

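The tests of the sources of the difference between experiments, of acinar RNA, of the prolactin list and of the standard errors were chosen after these results were seen, and the counts over other splits of the samples before.

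In experiment b, 28 of 284 groups of 5 libraries (9.86%) held a library far from the other 4 by Dixon's ratio of its gap to the range. For independent values with a normal spread, chance gives about 1 in 20. Here the genes were taken as counts without logs and share the same libraries, so the excess does not show more outliers than chance. Control_b replicate 2 accounted for 9 of them: Myc (ratio 0.777; 136 normalized counts against 19.9 to 45.9 in the other controls), Pkm (0.771), Atp5a1 (0.71), Atf4 (0.827), Mki67 (0.808; 211 against 57.8 to 87.2), Celf4 (0.793), Gdf15 (0.843), Kdr (0.75) and Rpl27 (0.755). Tph1 in KO_b replicate 2 had a ratio of 0.885, with 2211 normalized counts against 32.0 to 282 in the other knockouts, and that library also stood apart for Csf2rb2 (0.831), Crispld2 (0.711) and Cxcl10 (0.846). KO_b replicate 1 did so for Upk3a (0.832), Ghr (0.847) and the share of the insulin genes (0.71; 8.41% against 9.80% to 10.4%). KO_b replicate 3 stood apart for Atf4 (0.713), Krt7 (0.75) and Itgam (0.779), and KO_b replicate 4 for Rgs8 (0.747). Among the controls, replicate 1 stood apart for Ins1 (0.799) and Aldoa (0.769), replicate 3 for Sdf2l1 (0.718) and Lyz2 (0.731), replicate 4 for Smad3 (0.854), Fdft1 (0.714) and Jun (0.87), and replicate 5 for Cdh19 (0.752).

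The effect of the knockout differed between the experiments for 223 genes by limma's interaction test. The largest differences, experiment b minus experiment a, were 3.09 for Sgcz, 2.69 for Nnat, 2.63 for Vsnl1, 2.56 for Dapl1 and 2.54 for Trpc4, and -9.55 for Tph1, -9.24 for Esr1, -7.78 for Cldn8, -7.31 for Dnah8 and -7.19 for Gbp11. Of the lists, 9 passed the preset camera test, and with an estimated correlation beta cell identity alone did (adjusted p = 0.0451), the others lying between 0.0509 and 0.841. Their median differences were -1.39 for acinar markers, 0.62 for alpha cell markers, 0.36 for beta cell identity, 0.12 for cholesterol synthesis, 0.14 for exocytosis, 0.72 for immediate early genes, -0.39 for oestrogen response, -2.16 for prolactin and growth hormone response and -0.23 for the unfolded protein response.

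A difference between the controls is a candidate for the source of these 223 genes, of which 90.1% passed the threshold in experiment a and 13.0% in experiment b. The controls differed more between experiments than the knockouts for 60.5% of them (95% interval 53.8 to 67.0), for 74.2% (66.9 to 80.7) of the 167 with a lower effect in experiment b and for 19.6% (10.2 to 32.4) of the 56 with a higher effect. The intervals of such shares, here and below, treat genes of the same libraries as independent. They are likely too narrow, as for the prolactin list, with an estimated correlation of 0.394 between genes. Across the other genes tested, the control and the knockout differences between experiments correlated (Pearson 0.617 over genes, which are not independent replicates), so a shift common to both groups was present and these shares cannot name a source. For the prolactin list, 81.2% of 16 members (54.4 to 96.0) were higher in Control_b than in Control_a, against 52.4% of all genes tested. Of the members that rose in experiment a, 11 of 11 were higher in Control_b, against 626 of 796 other genes that rose there (78.6%). Genes that rose in experiment a share Control_a in both comparisons, which raises both shares. In experiment a both groups received tamoxifen, so neither tamoxifen nor the experiment alone accounts for a rise from Control_a to KO_a. Cre and the knockout changed together there and cannot be told apart. Neither control was labelled a knockout, so the knockout alone does not account for list members higher in Control_b than in Control_a. Between these controls Cre, tamoxifen and the experiment changed together and cannot be told apart as sources. The Cre line is not given in the sources used here.

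Of 100 splits of the 16 libraries within each experiment, 4 gave as many genes for that difference, the real one included, with 223 genes in the real split and up to 699 in another. Of the 4 other splits that kept all 3 knockouts of experiment a together, 3 gave as many (699, 377 and 279 genes) and 1 gave 117. The 95 splits that broke them up gave at most 3. Each such split removes the effect of 1 experiment or of both, so the splits say nothing about chance for the difference. For experiment b, 1 of 100 splits gave as many genes, the real one (395, highest other 3), and for both experiments together 1 of 100 (2377, highest other 385). This is the lowest share that 100 splits allow, and it argues against a random division of these libraries for both. Where libraries of a group are technical replicates, such splits cannot exclude a chance difference between a few animals. The 10 splits of experiment a are too few for a share under 0.05, with 1566 genes in the real split, the 1 that reached that count, and 0 in the highest other.

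Lower acinar markers in KO_b could account for genes that passed in experiment b. With the acinar level as a covariate, the changes of the 395 genes kept a median of 96.9% of their size (quartiles 86.7 to 108%). For these genes this argues against acinar RNA as the whole cause, but only weakly. They were selected without the covariate, where genes that vary with the acinar level within a group seldom pass, as with none of the 18 acinar markers. The covariate left 32 calls, as the median size went from 0.69 to 0.64 and the median standard error from 0.14 to 0.19. In experiment a without Control_a replicate 3, acinar markers had a median of 0.73, and 345 of 387 genes (89.2%, 85.6 to 92.1) kept the sign they had in experiment b. A part of the changes may still come from acinar RNA.

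Fewer genes passed in experiment b than in experiment a, with 5 libraries per group against 3. The values argue against a larger standard error in experiment b: the median ratio of the standard errors, b over a, was 0.869 over the 13057 genes tested in both and 0.972 for the genes past the threshold in experiment a (quartiles 0.817 to 1.19), of which 45.4% (42.9 to 47.9) had the larger one in experiment b. With simulated reads, 1.5-fold changes were recovered for 28.4% of genes in experiment b and 7.46% in experiment a. The simulation drew genes independently and changed far fewer genes than passed in experiment a, so it may understate recovery there. The genes past the threshold in experiment a had a median change of 0.87 there and of 0.31 in that direction in experiment b, where selection in experiment a raises the first. A smaller effect against controls with Cre was not tested apart from the experiment.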

How the results depend on the processing

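Fits with edgeR on recovered reads, without the libraries that stood apart (Control_a replicate 3 and Control_b replicate 2), with the acinar covariate and without KO_b replicate 1 in edgeR were chosen after the data were seen. No cause was tested for the changes below unless stated. Hdac3 kept its direction and its call under all alternatives run in experiment a and over both experiments, and its direction in experiment b. There its log2 fold change was -0.60 with quantile scaling (adjusted p = 0.0571), -0.61 without trend (0.086), -0.61 without a filter (0.0597), -0.61 with edgeR (0.0506), -0.63 with edgeR without KO_b replicate 1 (0.0894) and -0.53 with the acinar covariate (0.342), over a range of 0.00858 to 0.342. Leaving out each library gave -0.70 to -0.50 in experiment b, -0.77 to -0.65 in experiment a and -0.70 to -0.58 over both.

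The count of genes in experiment a was 1009 without trend and 597 to 1797 without each library. In experiment b it was 923 with DESeq2, 223 without trend, 32 with the acinar covariate, 210 with edgeR without KO_b replicate 1, 658 with all 16 libraries in 1 fit, 256 with a fold of at least 1.5, and 130 to 573 without each library. Over both experiments it was 1240 with the acinar covariate, 800 with a fold of at least 1.5, 202 past the threshold and the same way in each experiment alone, and 1725 to 2633 without each library. For the difference it was 351 with DESeq2, 124 with limma-voom and 121 to 365 without each library. By edgeR the counts were 1562, 377, 2297 and 205. Without the libraries that stood apart they were 1471, 573, 2057 and 231. The correlation of the experiments ranged from 0.342 to 0.482 without each library, and was 0.466 for genes past the threshold in either experiment and 0.444 for genes above the median of expression.

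With an estimated correlation, 0, 0 and 0 lists passed in experiment a, experiment b and both, and 1 for the difference. In experiment b 4 lists passed with a mean of at least 100. Without each library, 4 to 9, 4 to 8, 3 to 5 and 6 to 11 lists passed in experiment a, experiment b, both and the difference. By fry, which tests a list's genes without comparing them with others, 3, 0, 3 and 3 lists moved on balance in 1 direction and 18, 9, 18 and 7 in either. DESeq2 was not run for lists, since camera takes no such fit.

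The median of the acinar list turned to 0.0493 in experiment b, 0.0504 over both and 0.17 for the difference with the acinar covariate, which is built from that list. Over both experiments, Hes1, which did not pass, turned to 0.0418 with quantile scaling, 0.0042 without the libraries that stood apart and 0.0895 with the covariate, and ranged from -0.0913 to 0.0604 without each library. Rara, which did not pass, turned to 0.0273 without the libraries that stood apart.

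With the replicate number as a block, 673 genes passed in experiment a, 282 in experiment b, 1587 over both and 221 for the difference. The numbers did not pair the samples: the deviations of same-numbered libraries correlated at -0.34, 0.16 and -0.28 in experiment a and at 0.11, 0.08, -0.09, -0.06 and 0.18 in experiment b, and number 2 in experiment a and number 5 in experiment b had their own number as the best match. The planned tests of peaks near genes and their alternatives were not run. Depth limited the folds of genes near 0.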

Other observations

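The test of axonemal genes was chosen after the values of Dnah8 were seen, and the genes in the next paragraph were chosen after their values were seen.

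Several genes of experiment a that were not described above belong to the planned lists. Chgb, the granule protein chromogranin B, rose from 8094 ± 322 to 53174 ± 5686 normalized counts (SD, n = 3 each; log2 fold change 2.71, limma adjusted p = 4.04e-06). Doc2b, a calcium sensor of exocytosis, fell from 47.5 ± 11.1 to 16.7 ± 6.57 (log2 fold change -1.49, adjusted p = 0.0199). Among circadian clock genes, 4 of 19 fell, also when adjusted over the list alone (camera adjusted p = 0.384), and 0 to 6 without each library in turn (0 without Control_a replicate 2), with Per1 at -0.89, Cry2 at -0.95, Nr1d1 at -0.85 and Bhlhe41 at -0.95. Rph3a, an effector of the granule protein Rab3a, rose by 3.65 in experiment a and had a log2 fold change of -1.07 in experiment b (difference -4.72, adjusted p = 0.0285). Mki67, a marker of dividing cells, fell by 1.23 in experiment a (adjusted p = 0.0443), and Cdkn1a, an inhibitor of the cell cycle, rose by 0.84 (adjusted p = 0.0495).

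Because Dnah8, an axonemal dynein, was among the largest differences, the hypothesis that genes of the ciliary axoneme may move together with the knockout was tested on 20 of them in experiment a. It was not borne out: 4 rose and 1 fell, with a camera p = 0.0854, and p = 0.134 with an estimated correlation. In experiment b the camera p was 0.303, over both experiments 0.129 and for the difference 0.183.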
